A study of Homo sapiens with 36 samples.

How the data were processed

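Total RNA from the mantle cell lymphoma lines Mino and Rec was measured on 36 Illumina bead arrays. The cells had been kept with the solvent DMSO alone or with z-VRPR-fmk at 50 µM for 24, 30, 36, 42, 48 or 54 h. Mino had 2 arrays for each of its 12 groups of treatment and time, and Rec had 1 array for each of its 12 groups. RNA was extracted with an RNeasy kit and labelled with the Illumina TotalPrep kit, per the labels' protocols.

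The deposited value table holds log2 signals per probe, from 3.05 to 15.78. The authors' background correction, scaling and software are not given in the sources used here. The deposited log2 values of the 24 Mino arrays share nearly 1 distribution, with array medians from 4.14 to 4.21, and those of the 12 Rec arrays share another, with medians from 4.53 to 4.57. The lines were therefore taken to have been scaled separately, and levels were not tested between them. Of 48107 probes in the table, 325 were empty on at least 1 array, with the same probes empty in both arrays of every one of the 18 time-matched pairs, and the 47782 complete probes were used. A second kind of file, per the file headers, gives the intensity of each single bead, deposited as the scanner wrote it with a code and a position. Each array had from 1021650 to 1127627 beads, with a median of 20 to 22 beads per code over 48324 codes. No source used here ties these codes to genes, so bead intensities served only as an alternative source of values. Intensities more than 3 scaled median absolute deviations from the median of their code were left out (4.0% to 5.76% of beads per array), and the rest were averaged per code, log2-transformed and quantile normalized. Similarities between arrays computed from the bead intensities and from the table correlated at r = 1.00 across pairs of arrays in each line.

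Gene names came from the array annotation. Of the probes, 30113 had 1 gene symbol, 8 had several and 17986 had none. Symbols were updated by Entrez ID from a RefSeq gene table (assembly GRCh38.p14) for 30074 probes, and 39 probes kept the annotation's symbol. Among complete probes, 29854 had 1 symbol, for 19922 genes, of which 6634 had more than 1 probe. The probe with the highest mean over all 36 arrays stood for its gene. A gene was tested in a fit where its probe lay above the median of all probes of the array on at least 25% of the arrays in that fit. Of the genes named in advance, BIRC3 was not analysed here.

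Fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided moderated tests) with Benjamini-Hochberg adjustment and a threshold of 0.05, and every adjusted p for a single gene is from limma. In Mino, 12 group means were fitted, and the treatment effect was the mean over the 6 times of z-VRPR-fmk minus DMSO. In Rec, treatment was fitted with time as a factor, so that each time gave 1 pair of arrays. The line difference was the Rec effect minus the Mino effect in a fit of all 36 arrays with time within line. Time dependence was the slope of the effect over time, and drift was the slope of the DMSO arrays alone, both per 10 h. Mino was also tested for any change over time (F test) and at each time alone, with the spread shared over the 12 groups. Precision is limited by the number of arrays. The labels do not say whether replicates or times were separate cultures, so p-values measure the spread between arrays only.

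Altogether 32 gene lists were written before the data were examined, from general knowledge, with 1277 genes, of which 1194 matched the array, counting a gene once per list. They cover MYC and NF-kB targets, B-cell receptor, MALT1 pathway, MALT1 substrate and Regnase-1 or Roquin genes, cell cycle, ribosome, stress, metabolism, interferon, lysosome, autophagy, MHC, histone and cytokine genes, B-cell, plasma cell and mantle cell lymphoma genes, and markers of other cell types. Lists with at least 5 tested members were tested in each line with limma's camera, 2-sided, with a preset correlation between genes of 0.01 and adjustment over the lists of that line. Further tests used an estimated correlation, fry, and an exact sign-flip test of the list medians of the pairs, whose smallest possible p is 4.88e-04 for the 12 Mino pairs and 0.0312 for the 6 Rec pairs. Counts of list members were also made with p adjusted over the list alone.

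Named genes followed a rule set before the data were examined. In each line they were the 10 highest and 10 lowest log2 fold changes among genes past the threshold with the same sign in every time-matched pair. For other comparisons they were up to 5 per direction, for genes called in both lines the 5 highest and 5 lowest by the mean of both changes, and for each list up to 4 called members. A set of 12 genes around MYC and MALT1 was reported whatever the result.

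The array barcodes in the labels show that the replicate number of a Mino sample marks its slide, so the number pairs the arrays, and a fit with the replicate as a block was also made. Deviations of the replicates from their group means correlated between groups at -0.04 to 0.35, with a median of 0.14 over 66 pairs of groups. Other alternatives were quantile, 75th percentile and cyclic loess normalization, no filter and a stricter filter (above the 70th percentile on at least 50% of arrays), every probe on its own, the mean of a gene's probes, eBayes with trend and robust settings, array weights, bead intensities, each Mino slide alone, other time terms, and leaving out each array or each time. The estimated correlation together with the replicate block was an alternative chosen after seeing the data.

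The same steps were tested on simulated data, drawn from the means and spreads of the real genes, with 67, 67 and 66 genes changed by 0.25, 0.5 and 1 on the log2 scale. For the Mino effect, with 13497 genes, 32.8%, 89.6% and 100% of these were recovered with 7 wrong calls. For the Rec effect, with 13666 genes, 5.97%, 61.2% and 95.5% were recovered with 7 wrong calls. For the line difference, with 13573 genes, 4.48%, 52.2% and 100% were recovered with 5 wrong calls. Slopes were recovered at 44.8%, 91.0% and 100% for the Mino time dependence (9 wrong calls) and at 68.7%, 95.5% and 100% for the Mino drift (5 wrong calls). In Rec they were recovered at 19.4%, 73.1% and 98.5% for the time dependence (3 wrong calls) and at 50.7%, 83.6% and 98.5% for the drift (8 wrong calls). Tables and bead files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.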

Results

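Gene expression was measured in Mino and Rec, established lines of mantle cell lymphoma, a B-cell cancer in which the cyclin gene CCND1 is usually activated by a translocation. The cells had been kept with DMSO alone or with z-VRPR-fmk at 50 µM. z-VRPR-fmk is a peptide inhibitor of MALT1, the protease that links the B-cell receptor to NF-kB. The series title names MALT1 activity and MYC signaling, and the comparisons ask which transcripts differed under the inhibitor in each line, whether the lines differed in that response, and whether it depended on time. Mino had 24 arrays (2 treatments, 6 times, 2 slides) and Rec had 12 arrays (2 treatments, 6 times, 1 slide). Values are the deposited log2 signals, whose distribution differed between the lines, and each array rested on 1021650 to 1127627 beads. Line and slide cannot be told apart for levels, since Rec was on a slide of its own, so levels are set side by side but were compared only within a line. An effect is z-VRPR-fmk minus DMSO.

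In Mino, the genes that rose most under z-VRPR-fmk included regulators of membrane proteins and lipids and an interferon-induced gene. RHBDF1, an inactive rhomboid protein that guides the sheddase ADAM17, rose from 5.38 ± 0.54 to 7.37 ± 0.57 (log2 signal, SD, n = 12 arrays each), a change of 1.99 (SE 0.20, adjusted p = 5.82e-06). OAS1, an antiviral enzyme induced by interferon, rose by 1.82 (SE 0.15, adjusted p = 6.17e-07). ABCA1, the transporter that exports cholesterol from cells, rose by 1.73 (SE 0.11, adjusted p = 6.59e-08), and APOD, a lipid-binding apolipoprotein, by 1.62 (SE 0.14, adjusted p = 9.80e-07). ELAPOR1, an endosome and lysosome protein, rose by 1.27, TP53INP1, a stress protein with a part in autophagy, by 1.03, and MYB, a transcription factor of immature blood cells, by 1.00 (largest adjusted p of these, 1.78e-06). The transcription factor CASZ1 and the membrane-bound chemokine CXCL16 each rose by 1.04, and the ion channel gene BEST3 by 0.97, with adjusted p values of 6.41e-05, 7.63e-04 and 1.58e-05. All of these genes were higher in 12 of 12 time-matched pairs, as the naming rule requires. Of the 1852 genes past the threshold in Mino, 773 had the same sign in every pair. The DMSO level of ELAPOR1 (4.09) lay below the median of the array medians in Mino (4.17), so the size of its rise depends on background.

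Among the genes that fell in Mino, PDE7B, which degrades cyclic AMP, went from 6.39 ± 0.60 to 4.17 ± 0.22 (SD, n = 12 arrays each), a change of -2.22 (SE 0.19, adjusted p = 1.12e-06). ADTRP, a membrane hydrolase of fatty acid esters, changed by -1.79 (SE 0.13, adjusted p = 2.88e-07) and RSPH1, a protein of motile cilia, by -1.50 (SE 0.09, adjusted p = 6.03e-08). The secreted nuclease DNASE1L3 changed by -1.47, the signalling ligand WNT10A by -1.38 and SLC16A9, of the monocarboxylate transporter family, by -1.35 (adjusted p = 2.26e-06, 2.82e-09 and 2.49e-05). Further falls were -1.29 for the receptor gene KISS1R, -1.28 for the NOD-like receptor gene NLRP11, -1.15 for the protease inhibitor SPINK2 and -1.13 for the collagen gene COL9A2, with adjusted p of at most 1.38e-04. Each was lower in 12 of 12 pairs, again by the naming rule. Under z-VRPR-fmk PDE7B and NLRP11 (4.16) lay at or below the median of the array medians (4.17), so background limits the size of their falls.

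Of 13497 genes tested in Mino, 1852 passed the threshold, 908 higher and 944 lower. The median size of these changes was 0.28, and 83 rose and 72 fell by at least 1.5-fold. With 75th percentile scaling the split was 1067 higher and 725 lower. Of the genes tested on both slides, 456 passed on slide 1 alone and 867 on slide 2 alone, with 331 shared in the same direction against 15.2 for independent lists. Across 13032 genes the effects on the slides correlated at r = 0.72, where genes are not independent replicates.

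**Figure D1:**
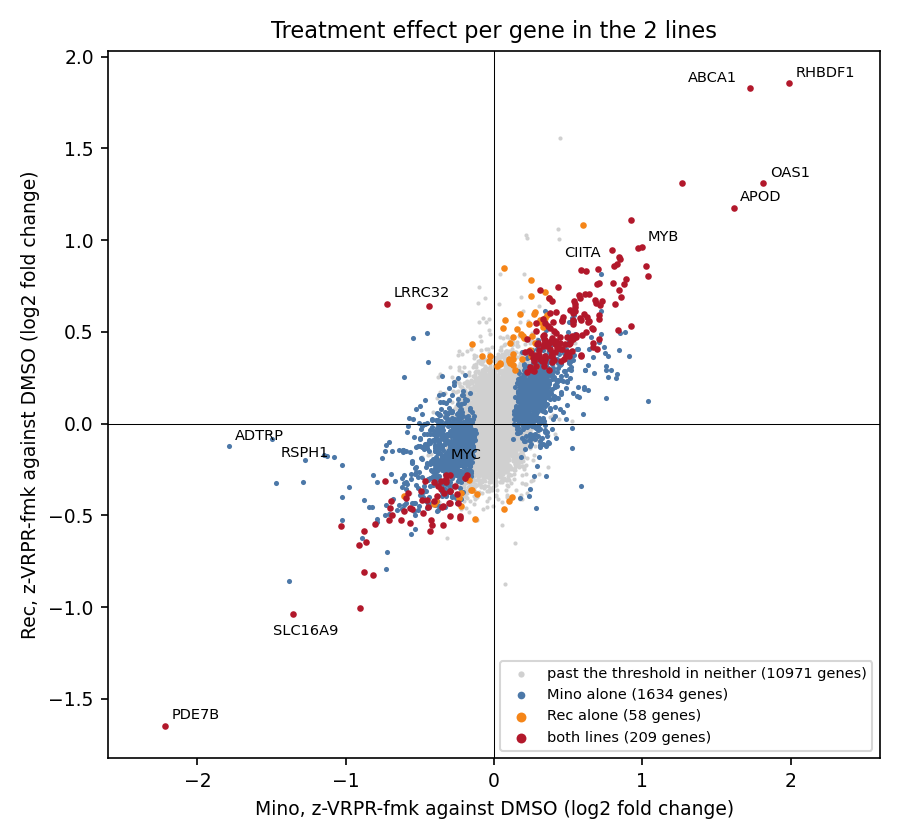
Log2 fold change of z-VRPR-fmk against DMSO in Mino (horizontal) and Rec (vertical), with 1 point for each of the 12872 genes tested in both lines, coloured by the line in which the gene passed the threshold. Of the genes past it in both lines, 150 lie at the upper right, 57 at the lower left and 2 (LRRC32 and HILPDA) at the upper left.

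MYC, the transcription factor of growth named in the series title, fell modestly in Mino. Its signal was 12.6 ± 0.23 in DMSO and 12.2 ± 0.19 under z-VRPR-fmk (SD, n = 12 arrays each, probe ILMN_1680618), a change of -0.33 (SE 0.07, adjusted p = 0.0064), lower in 11 of 12 pairs. A second MYC probe gave -0.36 (adjusted p = 0.0048). In Rec, MYC differed by -0.23 (SE 0.08, adjusted p = 0.188), lower in 5 of 6 pairs, which passed the threshold with the trend and robust settings of eBayes (adjusted p = 0.0126). The effects on MYC were not shown to differ between the lines (difference 0.11, adjusted p = 0.904).

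Other genes chosen in advance for their link to MYC, MALT1 or B cells went both ways in Mino. NFKBIA and TNFAIP3, inhibitors of NF-kB that NF-kB itself induces, rose by 0.31 (SE 0.09, adjusted p = 0.0291) and 0.37 (SE 0.10, adjusted p = 0.0185), each in 12 of 12 pairs. IRF4, a transcription factor of activated B cells, rose by 0.26 (adjusted p = 0.0311). The cell cycle inhibitor CDKN1A changed by -0.31 (adjusted p = 0.0174) and PRDM1, the regulator of plasma cell formation, by -0.43 (adjusted p = 0.0103), both lower in 12 of 12 pairs. The calls of NFKBIA and IRF4 ended when any of 9 and 11 of the 24 arrays was left out (adjusted p up to 0.0592 and 0.0608), and that of PRDM1 with the mean of its probes. MALT1 itself differed by 0.10 (adjusted p = 0.190), BCL10 by 0.02 (0.953), NFKB2 by 0.19 (0.419), CCND1 by 0.07 (0.316), BCL2A1 by 0.08 (0.446) and TXNIP by 0.23 (0.159, or 0.0105 with the replicate block), none past the threshold. In Rec none of these genes passed it. The estimates there were 0.14 for MALT1, -0.15 for BCL10, 0.14 for NFKBIA, 0.36 for TNFAIP3, 0.62 for NFKB2, -0.01 for IRF4, 0.08 for CCND1, -0.23 for CDKN1A, 0.06 for BCL2A1, -0.22 for PRDM1 and -0.00 for TXNIP, with adjusted p of at least 0.101. With trend and robust settings TNFAIP3, NFKB2 and CDKN1A also passed in Rec.

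**Figure D2:**
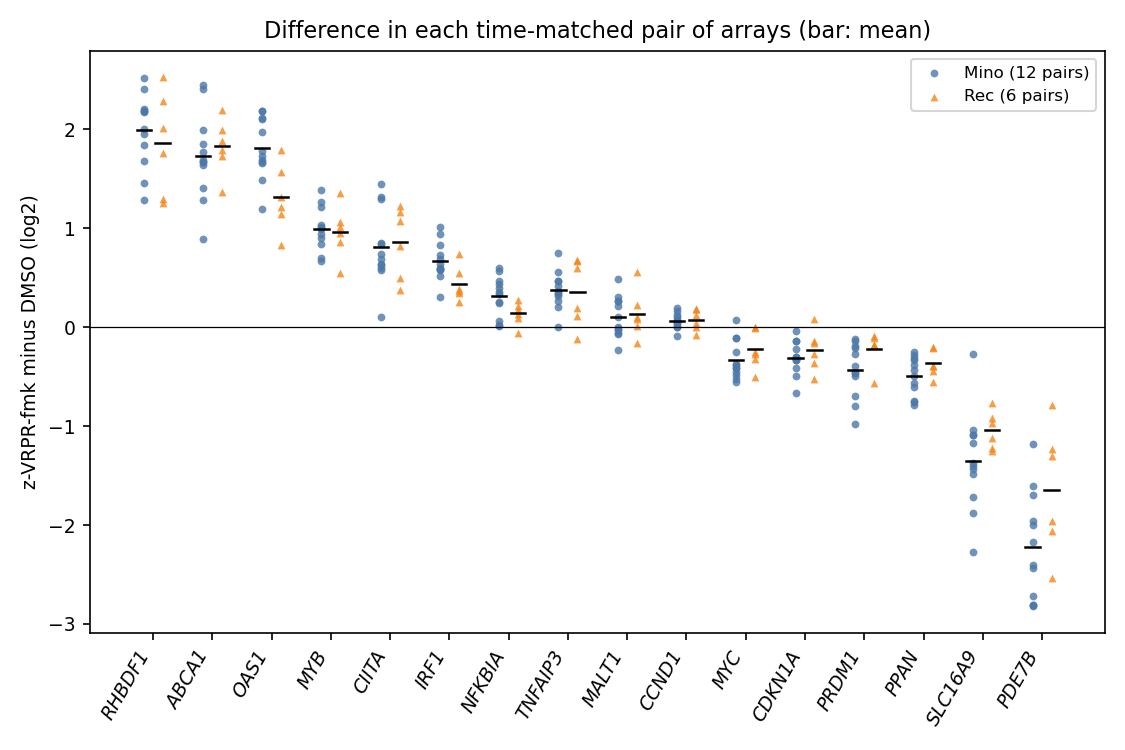
Difference in log2 signal between the z-VRPR-fmk and the DMSO array of each time-matched pair, with 1 point per pair (12 in Mino, 6 in Rec) and a bar for their mean, for 16 genes. RHBDF1, ABCA1, OAS1 and MYB lie above 0 and PPAN, SLC16A9 and PDE7B below 0 in every pair of both lines, while MYC is below 0 in 11 of the 12 Mino pairs and 5 of the 6 Rec pairs.

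Genes that MYC activates fell together in Mino. Of 59 measured MYC-activated genes, 26 fell and 0 rose (36 fell and 1 rose adjusted over the list alone), with the list median at -0.17 and below 0 in 12 of 12 pairs (camera adjusted p = 8.03e-12, and adjusted p = 0.0102 with an estimated correlation). They included PPAN (-0.49), NOP16 (-0.32), RRP12 (-0.31), all nucleolar proteins, and the nucleoside transporter SLC29A2 (-0.31). The fall of this list is not shown to follow the MYC transcript. At 24 h MYC differed by -0.11 and 0.08 in the 2 pairs, where the list medians were already -0.17 and -0.22. At later times both were below 0 in every pair. In DMSO alone MYC rose over time (0.15 per 10 h, limma adjusted p = 0.0397) while the list fell (median -0.20 per 10 h). Ribosome biogenesis genes, some of which are also on the MYC list, gave 27 of 69 lower and 0 higher (35 and 0 adjusted over the list alone). The median was -0.16, below 0 in 12 of 12 pairs (adjusted p = 1.48e-14, and adjusted p = 0.0141 with an estimated correlation). PPAN, NOP16 and RRP12 are among the genes on both lists. The MYC list was not tested without the shared genes, so the falls of these lists are not separate results. POLR1C, a subunit of RNA polymerases I and III, changed by -0.45 and LYAR, a nucleolar protein, by -0.35. Of 67 cytosolic ribosomal protein genes, the parts of the ribosome itself, 4 fell and 0 rose (3 and 0 adjusted over the list alone), namely RPS7 (-0.61), RPL29 (-0.60), RPL34 (-0.21) and RPS21 (-0.18), with the list median at -0.00 (adjusted p = 0.522).

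Interferon-stimulated and MHC class II genes rose together in Mino. Of 39 interferon-stimulated genes, 21 rose and 1 fell (23 and 2 adjusted over the list alone). The median was 0.24, above 0 in 12 of 12 pairs (adjusted p = 4.67e-12, and adjusted p = 5.85e-05 with an estimated correlation). Besides OAS1, PARP9 rose by 0.86, the antiviral gene SAMD9L by 0.85 and OAS3 by 0.73, and the guanylate-binding protein GBP2 fell by 0.32. Of 13 MHC class II genes, which present antigen to T cells, 11 rose and 0 fell (the same counts adjusted over the list alone). The median was 0.34, above 0 in 12 of 12 pairs (adjusted p = 9.59e-12, and adjusted p = 0.0102 with an estimated correlation). CIITA, the regulator of these genes, rose by 0.81, HLA-DPB1 by 0.61, HLA-DMB by 0.38 and HLA-DRB4 by 0.36.

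Several other lists shifted upwards in Mino by camera, but not with an estimated correlation. B-cell identity genes had 12 of 33 higher and 0 lower (14 and 2 adjusted over the list alone), with CD72 (0.92), BACH2 (0.81) and EBF1 (0.75), regulators of B cells. The median was 0.19, above 0 in 12 of 12 pairs (adjusted p = 2.84e-07, and adjusted p = 0.153 with an estimated correlation, or 0.0046 with the replicate block as well). Lysosome and cathepsin genes had 17 of 53 higher and 3 lower (19 and 4 adjusted over the list alone). The median was 0.11, above 0 in 12 of 12 pairs (adjusted p = 6.36e-05, and adjusted p = 0.115 with an estimated correlation, or 0.0204 with the replicate block as well). The lysosomal enzyme TPP1 rose by 0.40 and the cholesterol carrier NPC2 by 0.37, while the protease inhibitors CST7 and CST3 changed by -0.62 and -0.39. Autophagy genes had 7 of 32 higher and 1 lower (8 and 1 adjusted over the list alone), with WIPI2 at 0.64, BNIP3L at 0.31 and ULK1 at 0.26 besides TP53INP1. The median was 0.02 (adjusted p = 0.0172, and adjusted p = 0.170 with an estimated correlation). B-cell receptor and immediate-early genes had 7 of 34 higher and 0 lower (10 and 1 adjusted over the list alone), among them ETV5 (0.72), the ERK phosphatase DUSP6 (0.50), CD69 (0.45) and GFI1 (0.42). The median was 0.09, above 0 in 12 of 12 pairs (adjusted p = 0.0081, and adjusted p = 0.268 with an estimated correlation).

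Cell cycle lists also leaned upwards in Mino. Of 56 E2F and DNA replication genes, 7 rose and 1 fell (the same counts adjusted over the list alone), with E2F2 at 0.43, RRM2 at 0.31, UHRF1 at 0.21 and ASF1B at 0.20. The median was 0.10, above 0 in 9 of 12 pairs (adjusted p = 5.63e-05, and adjusted p = 0.170 with an estimated correlation). Of 63 G2/M and mitosis genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), among them MKI67 (0.36), ANLN (0.31) and CDC25B (0.30). The median was 0.08 (adjusted p = 0.0028, and adjusted p = 0.397 with an estimated correlation). Of 38 replication-dependent histone genes only H4C2 passed (0.28, none adjusted over the list alone). The median was 0.09 (adjusted p = 0.0081, and adjusted p = 0.308 with an estimated correlation). By fry, which does not compare a list with other genes, the G2/M and histone lists did not pass (adjusted p = 0.0578 and 0.0563). Of 17 MHC class I and antigen processing genes, HLA-E (0.30) and PSMB9 (0.24) rose and 0 fell (6 and 0 adjusted over the list alone). The median was 0.11 (adjusted p = 0.0138, and adjusted p = 0.308 with an estimated correlation).

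Lists of stress and metabolism leaned downwards in Mino, again not with an estimated correlation. Amino acid and ATF4 stress genes had 2 of 37 higher and 8 lower (2 and 10 adjusted over the list alone), with the amino acid transporter subunits SLC7A5 (-0.40) and SLC3A2 (-0.35) and, the other way, PPP1R15A (0.42). The median was -0.11 (adjusted p = 0.0011, and adjusted p = 0.213 with an estimated correlation). Unfolded protein response genes had 0 of 28 higher and 5 lower (0 and 6 adjusted over the list alone), with SEC24D at -0.37, SEC61B at -0.32 and XBP1 at -0.28. The median was -0.12 (adjusted p = 0.0019, and adjusted p = 0.213 with an estimated correlation). Glycolysis and hypoxia genes had 1 of 35 higher and 10 lower (the same counts adjusted over the list alone), with ADM at -0.62, PFKM at -0.39 and GPI at -0.32. The median was -0.13 (adjusted p = 0.0014, and adjusted p = 0.260 with an estimated correlation). Oxidative phosphorylation genes had 0 of 56 higher and 8 lower (0 and 9 adjusted over the list alone), led by ATP5MC3 (-0.39). The median was -0.07, below 0 in 12 of 12 pairs (adjusted p = 1.95e-05, and adjusted p = 0.213 with an estimated correlation).

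Further lists also leaned downwards in Mino, but not with an estimated correlation. Transcripts bound by the RNA-decay proteins Regnase-1 and Roquin had 1 of 15 higher and 7 lower (1 and 8 adjusted over the list alone), with TNFRSF4 at -0.71, CTLA4 at -0.40 and the transferrin receptor TFRC at -0.38. The median was -0.18, below 0 in 12 of 12 pairs (adjusted p = 0.0014, and adjusted p = 0.213 with an estimated correlation). NRF2 oxidative stress genes had 1 of 17 higher, HMOX1 (0.29), and 6 lower, led by SRXN1 (-0.25), with 2 and 8 adjusted over the list alone and a median of -0.06 (adjusted p = 0.0183, and adjusted p = 0.119 with an estimated correlation). Heat shock and proteasome genes had 0 of 37 higher and 4 lower (0 and 4 adjusted over the list alone), HSPA1L (-0.38), PSMA3 (-0.21), HSPD1 (-0.20) and HSP90AB1 (-0.14). The median was -0.06 (adjusted p = 0.0138, and adjusted p = 0.325 with an estimated correlation).

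The NF-kB target genes split in Mino, with 11 of 55 higher and 7 lower (11 and 7 adjusted over the list alone) and a median of 0.09 (adjusted p = 0.224). IRF1, an interferon regulatory factor, rose by 0.67 and the activation marker CD69 by 0.45, whereas WNT10A and the NF-kB inhibitor NFKBID fell by 1.38 and 0.40. Of 28 MALT1 pathway components 3 rose and 1 fell, PIK3CD (0.43), TRAF6 (0.24), CD79B (0.20) and CARD9 (-0.53). The median was 0.05 (adjusted p = 0.0857). Of 17 MALT1 protease substrates, PARP14 (0.48), TNFAIP3 (0.37) and ZC3H12B (0.22) rose and ZC3H12A, which encodes Regnase-1, changed by -0.60. The median was 0.05 (adjusted p = 0.247). Adjusted over the list alone, both lists kept 3 higher and 1 lower. Plasma cell genes had 3 of 21 higher and 5 lower (3 and 5 adjusted over the list alone), including FKBP11 (-0.56) and TNFRSF13B (-0.40). The median was -0.09 (adjusted p = 0.101). Mantle cell lymphoma genes had 6 of 23 higher and 3 lower (9 and 4 adjusted over the list alone), including SOX4 (0.77), SOX11 (0.46), CXCR4 (0.45) and FCGBP (-0.51). The median was 0.10 (adjusted p = 0.0766). Some of these lists did pass by tests that do not compare them with other genes, fry and the exact sign-flip test of the pair medians. Adjusted p by fry and by sign-flip was 0.0021 and 0.0043 for MALT1 pathway components (median above 0 in 11 of 12 pairs), 2.36e-04 and 0.0034 for mantle cell lymphoma genes (11 of 12) and 4.98e-04 and 0.0199 for plasma cell genes (3 of 12). MALT1 substrates passed by the exact sign-flip test alone (adjusted p = 0.0333).

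No shift against other genes was shown by camera in Mino for the remaining lists. Cytokine, chemokine and receptor genes had 2 of 37 higher and 6 lower (2 and 6 adjusted over the list alone), with ACKR3 at -1.03, IL2RB at -0.88 and TNFSF8 at -0.73, and their median of 0.01 differed in sign from their mean of -0.07 and from the test (adjusted p = 0.601). Sterol synthesis genes had 2 of 28 higher (LPIN1 0.27, ELOVL6 0.24) and 2 lower (MVD -0.20, FASN -0.17), and p53 targets 2 of 27 higher (TP53INP1, TRIM22 0.39) and 2 lower (FBXO22 -0.33, CDKN1A), with medians of -0.03 and -0.05 (adjusted p = 0.362 and 0.427) and the same counts adjusted over the list alone. Among 33 apoptosis regulators BIRC2 rose (0.23) and BCL2L10 fell (-0.24), neither adjusted over the list alone. The median was 0.05 (adjusted p = 0.243). For markers of other cell types, CD247 (-0.61) and CD8A (-0.49) fell and PRF1 (0.18) rose among 11 T and NK cell genes (median -0.11, adjusted p = 0.0960, or 0.0415 with the replicate block and 0.202 with an estimated correlation as well). TYROBP (0.42) rose among 10 myeloid genes, whose median of -0.01 differed in sign from their mean of 0.01 and the test (adjusted p = 0.801), and EPCAM (-0.23) fell among 9 fibroblast, endothelial and epithelial genes (median -0.02, adjusted p = 0.601). These 3 marker lists kept the same counts adjusted over the list alone. Without comparison to other genes, the apoptosis list passed by the exact sign-flip test (adjusted p = 0.0254, above 0 in 11 of 12 pairs) and the T and NK cell list by fry (adjusted p = 0.0218).

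**Figure D3:**
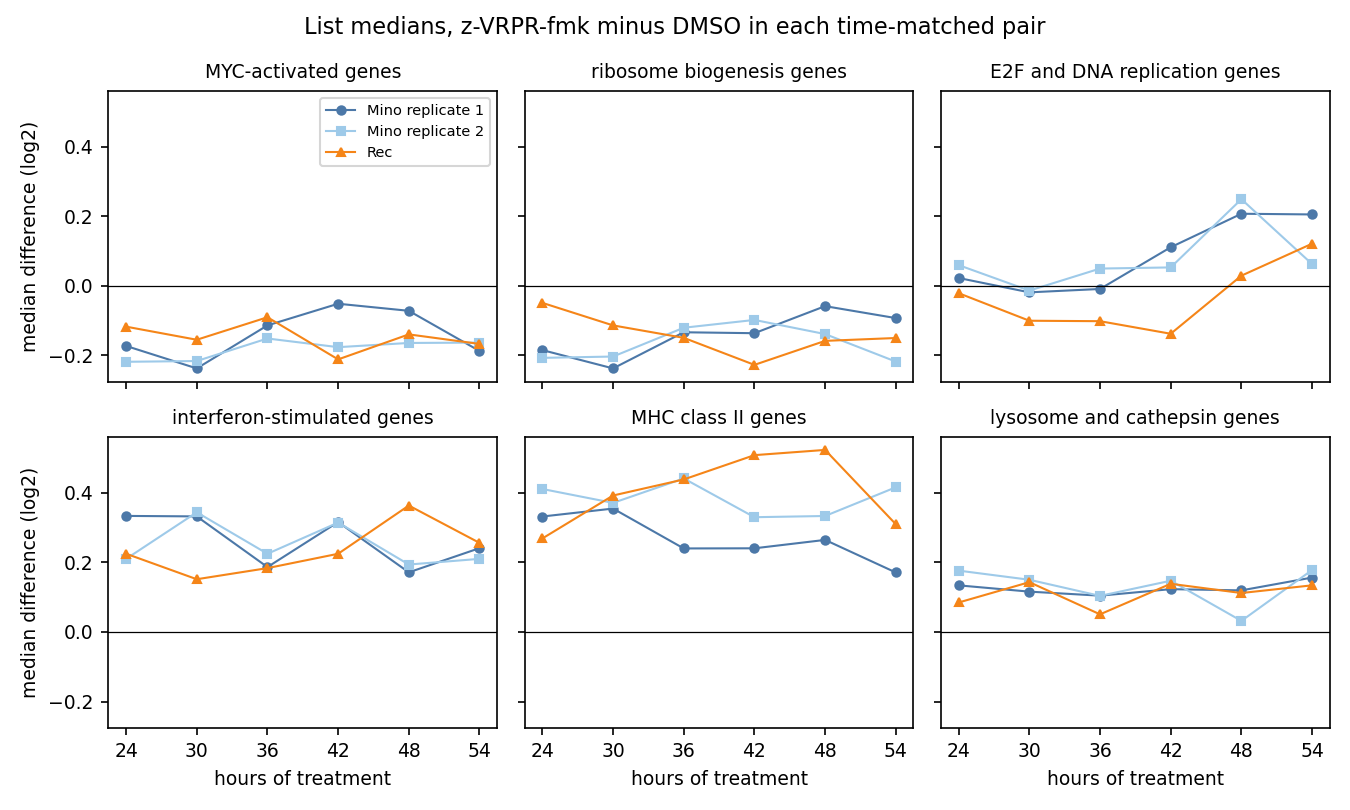
Median over the tested members of 6 gene lists of the log2 difference z-VRPR-fmk minus DMSO, per time-matched pair, against hours of treatment, for Mino replicates 1 and 2 and for Rec. The MYC-activated and ribosome biogenesis medians lie below 0 and the interferon, MHC class II and lysosome medians above 0 in all 18 pairs, while the E2F median is above 0 in 9 of 12 Mino pairs and 2 of 6 Rec pairs.

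In Rec, RHBDF1 rose from 5.95 ± 0.70 to 7.81 ± 0.51 (SD, n = 6 arrays each), by 1.86 (SE 0.17, limma adjusted p = 0.0033), and ABCA1 by 1.83 (SE 0.10, adjusted p = 4.10e-04). OAS1 rose by 1.31 (SE 0.12, adjusted p = 0.0031), KLHDC8B by 1.08 (SE 0.10, adjusted p = 0.0037) and MYB by 0.96 (SE 0.10, adjusted p = 0.0042). PDE7B changed by -1.65 (SE 0.21, adjusted p = 0.0093), SLC16A9 by -1.04 (SE 0.08, adjusted p = 0.0024), RASA4, which restrains RAS, by -0.86 (SE 0.11, adjusted p = 0.0085), FAM81A by -0.82 (SE 0.07, adjusted p = 0.0024) and KLHL14 by -0.59 (SE 0.06, adjusted p = 0.0042). Each of these genes went the same way in 6 of 6 pairs, as the naming rule requires. Each also passed the threshold when any 1 of the 12 arrays was left out. Under z-VRPR-fmk PDE7B (4.51) and RASA4 (4.07) lay below the median of the Rec array medians (4.55), so background limits the size of their falls.

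Other genes of the naming rule in Rec had the same sign in 6 of 6 pairs by that rule, but lost the call without some arrays. PAPPA, a protease that frees insulin-like growth factors, rose by 1.39 (SE 0.29), only just past the threshold, and lost the call without any of the 12 arrays (adjusted p up to 0.132). ELAPOR1 rose by 1.31 (adjusted p = 0.0357), the lymphatic growth factor VEGFD by 1.22 (0.0361), APOD by 1.18 (0.0240) and RAB37, of vesicle transport, by 1.11 (0.0226), and their calls ended without 10, 8, 8 and 10 of the arrays. PDIA2 changed by -1.0 (0.0240), the interleukin receptor chain IL2RB by -0.81 (0.0256), STPG3 by -0.66 (0.0172), CUEDC1 by -0.64 (0.0398) and FAM27C by -0.58 (0.0428), with calls ended without 6, 10, 6, 10 and 12 of the arrays. Adjusted p for these 9 genes then reached at most 0.120. In DMSO ELAPOR1 (4.52) and APOD (4.37) lay below the median of the Rec array medians (4.55), so the size of their rises depends on background.

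Of 13666 genes tested in Rec, 275 passed the threshold, 200 higher and 75 lower, and 63 rose and 9 fell by at least 1.5-fold. The count moved with single pairs, to 93, 74, 71, 71 and 86 without the arrays of 30, 36, 42, 48 or 54 h (70 to 93 without any single array of these times), and with the spread estimate, to 1035 with the trend and robust settings of eBayes.

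MYC-activated genes were lower in Rec too. Of 59, 3 fell (PPAN -0.36, SLC19A1 -0.34, NOP16 -0.28) and 0 rose (15 and 0 adjusted over the list alone). The median was -0.15, below 0 in 6 of 6 pairs (adjusted p = 3.19e-11, and adjusted p = 0.0465 with an estimated correlation). Of 69 ribosome biogenesis genes, 3 fell (POLR1C -0.41, PPAN and NOP16) and 0 rose (8 and 0 adjusted over the list alone). The median was -0.16, below 0 in 6 of 6 pairs (adjusted p = 2.72e-13, and adjusted p = 0.0744 with an estimated correlation). Interferon-stimulated genes had 9 of 37 higher and 0 lower (16 and 0 adjusted over the list alone), with SAMD9L at 0.91, PARP9 at 0.69 and OAS3 at 0.67. The median was 0.20, above 0 in 6 of 6 pairs (adjusted p = 1.53e-10, and adjusted p = 0.0306 with an estimated correlation). MHC class II genes had 9 of 13 higher and 0 lower (13 and 0 adjusted over the list alone), with CIITA at 0.86, HLA-DPB1 at 0.71 and HLA-DOA at 0.48. The median was 0.42, above 0 in 6 of 6 pairs (adjusted p = 2.59e-14, and adjusted p = 0.0744 with an estimated correlation). Lysosome genes had 4 of 53 higher (SGSH 0.48, NPC2 0.44, NEU1 0.37, TPP1 0.35) and 0 lower (14 and 1 adjusted over the list alone). The median was 0.14 (adjusted p = 2.68e-06, and adjusted p = 0.0306 with an estimated correlation). Autophagy genes had 2 of 31 higher (TP53INP1 0.86, WIPI2 0.55) and 0 lower (8 and 0 adjusted over the list alone). The median was 0.14 (adjusted p = 1.31e-04, and adjusted p = 0.0465 with an estimated correlation).

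B-cell receptor and immediate-early genes had 3 of 34 higher in Rec, LY9 (0.69), EGR3 (0.53) and GFI1 (0.49), and 0 lower (16 and 0 adjusted over the list alone). The median was 0.26, above 0 in 6 of 6 pairs (adjusted p = 2.28e-07, and adjusted p = 0.227 with an estimated correlation). Among 58 NF-kB target genes IRF1 alone passed (0.44, or 12 higher and 1 lower adjusted over the list alone). The median was 0.08, above 0 in 6 of 6 pairs (adjusted p = 0.0022, and adjusted p = 0.247 with an estimated correlation). B-cell identity genes had 4 of 34 higher, CIITA, BACH2 (0.65), CD72 (0.53) and TCL1B (0.40), and 0 lower (9 and 0 adjusted over the list alone). The median was 0.02 (adjusted p = 0.0141, and adjusted p = 0.247 with an estimated correlation). In the MHC class I list HLA-E rose by 0.40 (4 of 17 higher adjusted over the list alone). The median was 0.13 (adjusted p = 0.0141, and adjusted p = 0.118 with an estimated correlation). Regnase-1 and Roquin transcripts had 0 of 16 higher and TFRC lower (-0.39, or 1 and 6 adjusted over the list alone). The median was -0.23 (adjusted p = 0.0079, and adjusted p = 0.118 with an estimated correlation). For heat shock and proteasome genes FKBP4 of 38 fell (-0.38, or 2 adjusted over the list alone). The median was -0.08 (adjusted p = 0.0149). Of 56 oxidative phosphorylation genes and of 33 histone genes 0 passed either way, with medians of -0.05 and 0.08 (adjusted p = 0.0029 and 0.0456). For these last 3 lists the adjusted p was 0.247 with an estimated correlation. By fry the B-cell identity and histone lists did not pass in Rec (adjusted p = 0.0606 for both).

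No shift against other genes was shown by camera for the other lists in Rec. By fry, which makes no such comparison, apoptosis regulators (adjusted p = 9.02e-04, median above 0 in 6 of 6 pairs), NRF2 genes (0.0370, below 0 in 5 of 6) and myeloid markers (0.0329, above 0 in 5 of 6) passed. E2F genes had a median of -0.03 (adjusted p = 0.0904) and G2/M genes of -0.01 (adjusted p = 0.705), with 0 of 56 and 0 of 63 past the threshold by limma, also adjusted over the list alone. MALT1 pathway components (median 0.01, adjusted p = 0.705), MALT1 substrates (0.01, 0.831), unfolded protein response (-0.04, 0.327) and NRF2 genes (-0.06, 0.128) had 0 past it, and adjusted over the list alone 0, 6, 0 and 2. The PPP1R15A gene rose in the ATF4 list (0.41; median -0.06, adjusted p = 0.133), LPIN1 in the sterol list (0.29; -0.03, 0.484), TP53INP1 and TRIM22 (0.38) among p53 targets (-0.03, 0.484), and SOX11 (0.56) among mantle cell lymphoma genes (0.01, 0.373). BCL2L11, which promotes apoptosis, rose by 0.60 and BCL2L10 changed by -0.43 among apoptosis regulators (0.05, 0.268), and TNFRSF17 rose by 0.39 and AQP3 changed by -0.55 among plasma cell genes (-0.01, 0.746). Adjusted over the list alone these lists had 1 and 0, 1 and 0, 2 and 2, 6 and 4, 2 and 1, and 2 and 1 members higher and lower.

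In 5 lists of Rec the median, mean and test differed in sign, and none of these passed by camera or fry. They were cytosolic ribosomal protein genes (median 0.02, mean -0.00, test down, adjusted p = 0.861), glycolysis and hypoxia genes (-0.03, 0.02, down, 0.906), cytokine and receptor genes (0.05, -0.01, up, 0.359), T and NK cell markers (0.02, -0.04, down, 0.756) and fibroblast, endothelial and epithelial markers (-0.06, 0.03, up, 0.861). SLC2A3 (0.69) rose in the glycolysis list, IL4R (0.39) rose and IL2RB and ACKR3 (-0.56) fell in the cytokine list, CD247 (-0.48) fell among T and NK cell markers, and 0 genes passed in the others. Of 12 myeloid markers TYROBP rose by 0.45 (median 0.04, adjusted p = 0.373). Members higher and lower adjusted over the list alone were 0 and 2, 4 and 1, 7 and 4, 0 and 1, and 0 and 0 for these lists in order, and 1 and 0 for the myeloid list. Of the list members named as examples, OAS3 and BCL2L10 in both lines, CTLA4 and HSPA1L in Mino and AQP3 in Rec lay below the median of the array medians in 1 treatment, so background limits the size of their changes.

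Many of the same genes changed in both lines. Of 12872 genes tested in both, 150 were higher in both, against 13.7 for independent lists, and 57 were lower in both, against 5.2. RHBDF1, ABCA1, OAS1, APOD and ELAPOR1 rose most by the mean of both changes, and PDE7B, SLC16A9, PDIA2, IL2RB and FAM81A fell most, PDIA2 and FAM81A by 0.91 and 0.81 in Mino. No gene was higher in Mino and lower in Rec by limma, and 2 were lower in Mino and higher in Rec. These were LRRC32 and HILPDA, a lipid droplet protein induced by hypoxia (-0.44 in Mino, 0.64 in Rec, difference 1.08, adjusted p = 0.0385), the latter named after its values were seen. The lines share no arrays. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.59 (Spearman's rho 0.49), and the sign was the same for 67.2% of all these genes and for 90.5% of those called in Mino.

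Whether the lines differed in their response was tested directly, and 18 of 13573 genes passed, 13 with a higher effect in Rec and 5 with a lower one. ADTRP and RSPH1 fell in Mino but differed by only -0.12 and -0.08 in Rec, so that the Rec effect was higher by 1.66 (SE 0.20, adjusted p = 1.29e-04) and 1.42 (SE 0.23, adjusted p = 0.0056). LRRC32, a surface protein that holds latent TGF-beta, changed by -0.72 in Mino (lower in 11 of 12 pairs) and by 0.65 in Rec (higher in 6 of 6), a difference of 1.37 (SE 0.24, adjusted p = 0.0083) that lost the call without either Rec array of 36 h (adjusted p up to 0.0574). The metallothionein MT1G and PAPPA, whose Mino signals lay below the filter, differed by 1.67 (SE 0.33, adjusted p = 0.0303) and 1.44 (SE 0.23, adjusted p = 0.0056). CXCL9, a chemokine induced by interferon gamma, differed by -1.02 (adjusted p = 0.0341), QRSL1 by -0.63 (0.0303), DIO3, which inactivates thyroid hormone, by -0.58 (0.0083), SLCO1A2 by -0.52 (0.0385) and the receptor tyrosine kinase AXL by -0.37 (0.0473). CXCL9, AXL and SLCO1A2, like MT1G and PAPPA, lay below the median of the array medians in Mino in both treatments. For these 5 genes an effect in Mino could not be measured above background, so the difference is not shown to be one of response. In DMSO alone QRSL1 lay below it (4.13) and DIO3 only just above it (4.21), so background limits their values too. Without single arrays the calls of MT1G, CXCL9, QRSL1, SLCO1A2 and AXL ended for 5, 10, 6, 14 and 28 of them (adjusted p up to 0.181). With the replicate block 36 genes passed, 25 higher and 11 lower, among them all 18. The count was 7, 5 and 9 without either Rec array of 30, 36 or 42 h, and 5, 3, 7, 10 and 11 without all arrays of 30, 36, 42, 48 or 54 h. Quantile normalization gave 15 higher and 2 lower.

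Several lists leaned apart between the lines by camera, none with an estimated correlation. E2F and DNA replication genes had a lower effect in Rec (median difference -0.12, adjusted p = 2.16e-09), as had G2/M genes (-0.08, adjusted p = 1.09e-04) and B-cell identity genes (-0.14, adjusted p = 0.0031). B-cell receptor and immediate-early genes had a higher effect in Rec (0.10, adjusted p = 0.0058), as had glycolysis and hypoxia genes (0.07, adjusted p = 0.0030), MHC class II genes (0.08, adjusted p = 0.0205) and plasma cell genes (0.05, adjusted p = 0.0192). With an estimated correlation the adjusted p was 0.316 for plasma cell genes and 0.431 for the other 6 lists. MYC-activated genes were not shown to differ (0.02, adjusted p = 0.685).

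The effect in Mino depended on time for 1 of 13497 genes. ELAPOR1 rose further with time, by 0.63 per 10 h (SE 0.09, adjusted p = 0.0344), a call that ended without any of 15 of the 24 arrays (adjusted p up to 0.225) and under each other normalization. By limma's F test for any change over the 6 times 0 genes passed, and for the slope 939 had an unadjusted p under 0.05. With the replicate block 10 genes passed for the slope, 2 rising and 8 falling. In Rec 0 of 13666 genes passed for the slope by limma, with 474 at an unadjusted p under 0.05. At single times in Mino, with 2 arrays against 2, 25 genes passed at 24 h, 52 at 30 h, 16 at 36 h, 59 at 42 h, 35 at 48 h and 86 at 54 h, and with the replicate block 92, 118, 51, 160, 122 and 248. The E2F list effect rose with time in Mino by camera (median slope 0.06, adjusted p = 2.68e-09, and adjusted p = 0.289 with an estimated correlation). By camera the effect also rose with time for the MYC-activated, NF-kB, ribosome biogenesis, ATF4 and heat shock lists (median slopes 0.03 to 0.05, adjusted p of at most 0.0163) and fell for glycolysis and hypoxia genes (-0.07, adjusted p = 4.60e-04) and T and NK cell markers (-0.07, adjusted p = 0.0078). In Rec it rose for E2F and G2/M genes (0.04 for both, adjusted p = 0.0390). None of these lists passed with an estimated correlation.

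The DMSO cultures themselves changed over time. In Mino 4185 of 13497 genes drifted, 2206 upwards and 1979 downwards (1632 and 2776 with 75th percentile scaling). PFKFB4, a regulator of glycolysis, rose by 1.53 per 10 h (SE 0.20, adjusted p = 2.31e-05), the hypoxia-induced COXFA4L2 by 1.42 (1.53e-06), APOD by 1.40 (4.52e-08), LRRC32 by 1.24 (2.56e-08) and ELFN2 by 1.18 (5.09e-05). POLR2L, a subunit of RNA polymerases, changed by -0.72 per 10 h, SNORD91A by -0.64, the cytokine TNF by -0.62, ATAD3B by -0.60 and ZNF326 by -0.59 (adjusted p of at most 3.19e-04). Of the E2F genes 46 of 56 fell and 0 rose (median -0.22 per 10 h, adjusted p = 1.04e-21, and adjusted p = 0.0074 with an estimated correlation), and of the MYC-activated genes 42 of 59 fell and 2 rose (-0.20, adjusted p = 4.15e-17, and adjusted p = 0.0043 with an estimated correlation). Ribosome biogenesis genes (49 of 69 lower, 1 higher) and heat shock and proteasome genes (26 of 37 lower, 0 higher) also fell, and interferon-stimulated genes rose (15 of 39 higher, 2 lower), with adjusted p = 0.0112, 0.0360 and 0.0079 with an estimated correlation. In Rec 8 of 13666 genes drifted by limma, 7 upwards and 1 downwards, and 1627 had an unadjusted p under 0.05. With fewer arrays in Rec, the lower count does not show that its cultures changed less. By camera E2F (median -0.12 per 10 h, adjusted p = 1.07e-14), G2/M (-0.13, 1.15e-17) and glycolysis genes (-0.20, 7.73e-07) fell in Rec. ATF4 genes rose there (0.19, 2.40e-11). None of these lists passed in Rec with an estimated correlation (adjusted p of at least 0.118). FERMT2, an integrin activator, rose by 1.18 per 10 h (SE 0.16, adjusted p = 0.0211), NLRP11 by 0.81 (0.0067), BEX2 by 0.72 (0.0211), WARS1 by 0.61 (0.0381) and WIPI1, of autophagy, by 0.55 (0.0211), and S100A4 changed by -0.37 (0.0211). The call of NLRP11 ended without the DMSO array of 24 h (adjusted p = 0.101), and those of FERMT2, BEX2 and WIPI1 without that array, the DMSO array of 48 h or the z-VRPR-fmk array of 30 h, and for FERMT2 and BEX2 also without the DMSO array of 30 h (adjusted p up to 0.138). WARS1 lost it without any of 8 arrays and S100A4 without any of 5 (adjusted p up to 0.181). The count itself was 0, 2 and 1 without the DMSO array of 24, 30 or 48 h, and 1 and 5 without the z-VRPR-fmk array of 30 or 48 h.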

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

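The tests of the alternation of array positions and of the size of the response in Rec were chosen only after the result was seen. The genes past the threshold under z-VRPR-fmk were weighed against technical explanations. With treatment swapped within time-matched pairs, at most 11 genes passed in Mino against 1852, and at most 0 in Rec against 275 by limma. The real arrangement was the 1 of 100 and the 1 of 32 that gave as many. These values argue against chance differences between single arrays. A difference shared by all arrays of a treatment, as from 1 culture per treatment, would pass this test, and the labels do not exclude it. A gradient along the slide was argued against, since for 99.46% of the called genes in Mino and 100% in Rec the step to the DMSO array in the next position went opposite to the effect. z-VRPR-fmk took the earlier position in 0 of the 18 pairs, so an effect of alternating positions cannot be told apart from the treatment, which the fixed order keeps open.

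Fewer genes passed the threshold in Rec than in Mino. Over all 12872 genes tested in both lines, with none chosen by effect, the response size (root of the mean product of the pair differences at different times, log2) was 0.133 in Rec, a difference of -0.0221 from Mino slide 1 (jackknife SE 0.0071 over 6 times) and of -0.0307 from slide 2 (SE 0.0071), each slide having as many arrays as Rec. In Rec and on each Mino slide, 200 genes were chosen without 1 time and read at that time. Genes chosen in Rec kept 104% and 102% of their median effect on slides 1 and 2. Their effect was nevertheless lower there than in Rec at 4 of 6 times on each slide. Genes chosen on slides 1 and 2 kept 72.1% and 68.7% in Rec, lower at 6 of 6 times for each slide. These values argue against fewer arrays as the only reason. Fewer arrays still lower the count: of genes tested on both Mino slides, 456 passed on slide 1 alone and 867 on slide 2 alone. The fit of both slides gave 1852 and Rec 275. Part of the gap therefore goes with the number of arrays. A spread of log2 values in Rec at 97.5% of that in Mino argues against a scale compressed over all genes. That spread says little of low signals, and array medians were higher in Rec (4.53 to 4.57) than in Mino (4.14 to 4.21). Smaller changes of dim genes through a higher background in Rec therefore stay open. A smaller response in Rec may be part of the difference, a hypothesis found and tested on the same data, and as line and slide cannot be told apart, a difference between slides stays open.

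The effect of z-VRPR-fmk differed between the lines for named genes, by the Rec effect minus the Mino effect: MT1G (1.6746), ADTRP (1.6649), PAPPA (1.4360), RSPH1 (1.4155) and LRRC32 (1.3728) higher in Rec, and CXCL9 (-1.0171), QRSL1 (-0.6341), DIO3 (-0.5801), SLCO1A2 (-0.5211) and AXL (-0.3655) lower. Regrouping the 18 pair differences gave at most 3 genes in other draws, against 29 for the real lines in that fit (1 of 100). This argues against chance differences between single pairs. Only the real grouping keeps the Rec slide whole, so a chance difference shared by that slide or its cultures would pass this test. Among gene lists, the median difference by camera was -0.1247 for E2F and DNA replication genes, -0.0827 for G2/M genes, -0.1391 for B-cell identity genes, 0.0977 for B-cell receptor and immediate-early genes, 0.0702 for glycolysis and hypoxia genes, 0.0469 for plasma cell genes and 0.0762 for MHC class II genes, none past the threshold with an estimated correlation. MT1G, PAPPA, CXCL9, AXL and SLCO1A2 lay below the median of the array medians in Mino in both treatments, where no effect can be measured. Their values are therefore not shown to be differences of response. In DMSO QRSL1 lay below that median and DIO3 only just above it. Whether the line or its slide underlies these differences is not resolved by the design.

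Single Rec pairs stood far from the other 5. RAB37 differed by 0.0335 at 36 h, against 1.1433 to 1.4962 in the others. PRDM1 differed by -0.5627 at 30 h, against -0.19 to -0.09. The median of the sterol synthesis list was 0.1490 at 54 h, against -0.11 to -0.04. These were 3 of 64 values tested (4.69%), and chance gives about 1 in 20.

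Probes without a gene name, which the comparisons did not use, also gave a signal. Of 8909 such probes tested in Mino, 177 passed the threshold (65 higher, 112 lower), 1.99% against 13.7% of genes, and in Rec 3 of 8437 did.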

How the results depend on the processing

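Tests combining an estimated correlation with the replicate block were chosen only after the result was seen. The cause of the changes below was not tested, except where the alternative's construction gives it: bead-level values count bead codes and not genes, every probe counts probes, and slides alone or fewer times leave fewer arrays.

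The Rec count (275) was 163 with no filter, 660 with the stricter filter, 1035 with trend and robust settings, 1079 with bead-level values, 46 with no time term and 110 with linear time. Without 30, 36, 42, 48 or 54 h it was 93, 74, 71, 71 and 86, and without single arrays 70 to 194. The line difference (18) was 5 with the stricter filter, 32 with array weights, 29 with bead-level values, 36 with the replicate block, 1 and 10 with slide 1 or 2 alone, 5, 3, 7, 10 and 11 without 30, 36, 42, 48 or 54 h, and 5 to 25 without single arrays. The Mino count (1852) was 456 and 877 on slide 1 or 2 alone, and 1516 to 1751 without single arrays.

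The Mino time dependence (1) was 0 under quantile, 75th percentile and cyclic loess normalization and the stricter filter, 3 with every probe, 12 with trend and robust settings, 3 with bead-level values and 10 with the replicate block. It was 0, 2, 0, 0 and 0 without 24, 36, 42, 48 or 54 h, and 0 to 2 without single arrays. The Rec time dependence was 0 to 0 without single arrays by limma. The Mino drift (4185) was 6695 with bead-level values and 3380 to 4276 without single arrays. The Rec drift (8) was 32 with the stricter filter, 17 with every probe, 19 with the mean of probes, 76 with trend and robust settings, 129 with bead-level values, 0, 0, 15, 0 and 5 without 24, 30, 42, 48 or 54 h, and 0 to 12 without single arrays.

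Genes called in both lines (207 in the same direction) were 134 with no filter, 442 with the stricter filter, 649 with trend and robust settings, 683 with bead-level values, 137 with slide 1 alone and 42 at 1.5-fold or more. Single Mino times gave 92, 118, 51, 160, 122 and 248 genes with the replicate block. MYC in Rec (-0.23) passed the threshold with trend and robust settings. NF-kB targets in Rec lost the call with an estimated correlation (adjusted p = 0.247). By the exact sign-flip test no Rec list passed, MYC-activated genes and NF-kB targets included: 6 pairs allow no p under 0.0312, and the lowest adjusted p, 0.0832, was shared by 12 lists, so this is set by the number of pairs.

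The replicate block also brought TXNIP (0.0105), KLHDC8B (0.0018), WIPI1 (0.0403) and the T and NK cell list (0.0415, but 0.202 with an estimated correlation as well) past the threshold for the Mino effect. For the line difference, the genes it added included CASZ1 (0.0126), KISS1R (0.0196), DNASE1L3 (0.0226), COL9A2 (0.0275) and EBF1 (0.0455). Of the other list results, 24 lost the call with an estimated correlation. Another 36 kept their side of the threshold, mostly lists that had no call by camera. The calls kept were those of ribosome biogenesis, interferon and MHC class II genes in Mino, and of interferon, lysosome and autophagy genes in Rec. With the replicate block as well, 13 lists lost the call in Mino and 17 kept their side, again mostly lists without a call. Of the named gene results, 100, 101 and 102 kept direction and side under quantile, 75th percentile and cyclic loess normalization, and 4, 3 and 2 lost the call. No direction of a called result reversed. Signal near background limits what could be tested: 13497 of 19922 genes passed the filter in Mino.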

Other observations

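The test of culture time was chosen only after the result was seen. The effect of z-VRPR-fmk in Mino resembled the drift of the DMSO cultures weakly across 13497 genes, which are not independent replicates (r = 0.154). Of the 989 genes called for both, 700 had the same sign. By median, 21 of 32 lists went the same way. Among these were MYC-activated (-0.20 per 10 h in DMSO), ribosome biogenesis (-0.16), interferon (0.09) and MHC class II genes (0.15). E2F, G2/M, ATF4 and glycolysis genes were among those that went the other way. For lists that went the same way, a part played by culture time stays open. Treated cultures further along the same time course are argued against as the whole cause, since E2F genes fell over time in DMSO but were higher under z-VRPR-fmk (list median 0.0966, exact sign-flip p = 0.0059 over 12 pairs, above 0 in 9). Against other genes the E2F list passed by camera but not with an estimated correlation (adjusted p = 0.170, or 0.192 with the replicate block as well). The E2F values speak only of treated cultures being further along. For lists that went the other way, treated cultures less far along were not tested, so culture time stays open there too.

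ABCA1 is a target of LXR, the oxysterol receptor, and a list of 17 LXR targets was written to ask whether these rose together. The median was 0.0222 in Mino and 0.0382 in Rec (camera p = 0.310 and 0.0264, or 0.361 and 0.0682 with an estimated correlation), with 2 members higher and 0 lower in each line by limma. SREBF1 and SCD, which other lists hold, had estimates below 0 (-0.07 and -0.08 in Mino, -0.13 and -0.04 in Rec), none past the threshold. Without them the median was 0.0526 in Mino and 0.2214 in Rec, so leaving them out raised it. By camera the Rec list passed 0.05 with and without them, and the Mino list did not in either case. These values leave it open whether LXR could be involved.

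APOD and TP53INP1 can be induced by FOXO transcription factors, which are held back by growth factor signalling. A list of 34 other FOXO targets, of which TXNIP and BCL2L11 had been seen before, had 8 of 29 members higher in Mino and 10 of 30 in Rec, with 0 lower by limma. The median was 0.1933 in Mino and 0.1735 in Rec, above 0 in 12 of 12 and 6 of 6 pairs (camera p = 2.61e-06 and 1.31e-08, or 0.0224 and 0.0013 with an estimated correlation). KLHL24 rose by 0.85 and 0.90, FBXO32 by 0.70 and 0.76 and KLF2 by 0.53 and 0.56, genes chosen after their values were seen. Without the 5 members that other lists hold, the median was 0.2125 and 0.1749. FOXO activity may therefore be raised under z-VRPR-fmk, a hypothesis that transcript levels alone leave open. In Mino DMSO cultures APOD and TP53INP1 also rose over time (1.40 and 0.92 per 10 h, limma adjusted p = 4.52e-08 and 5.07e-08). Neither passed for drift in Rec. The drift of the FOXO list was not tested in either line, so a part played by culture time stays open.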
